A study of Homo sapiens
Mus musculus and Mus musculus and Homo sapiens with 3 samples.

How the data were processed

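Human and mouse pluripotent stem cells that had been differentiated towards motor neurons as embryoid bodies, which are floating aggregates of cells, were profiled by droplet-based 3' single-cell RNA sequencing. Per the labels, the cells carried a lentiviral GFP reporter with a short barcode, were dissociated with papain and DNase I, and were sorted for GFP before library preparation with 10x Genomics reagents. Sampling was every 24 h in mouse and every 48 h in human. The deposited files held raw UMI counts per gene and cell, so the unit of every value is counts. The submitters' processing notes named Cell Ranger 3.1.0 with the builds mm10 and hg38. The gene annotation and the step that removed empty droplets were not given in the sources used here.

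The 3 samples gave 4 library parts. Human replicate 1 (the line NCRM1, an induced pluripotent line) and mouse replicate 1 (C57BL/6 embryonic stem cells) were the parts of 1 mixed library and were deposited apart by species. Human replicate 2 (RUES1, given as an induced pluripotent line in the labels) and mouse replicate 2 were libraries of their own. The numbers 1 and 2 are names only, apart from the mixed library that both parts numbered 1 share. The human libraries were of different lines, so their spread also holds a line difference. The labels do not state that the mouse libraries came from separate cultures. Each p-value of a gene test or of a permutation test of shares thus measures only the spread between these libraries. The Fisher test was over cells, and the permutation tests of HOX genes and pseudogenes were over genes. The files gave no day for a cell and no barcode sequence, and a planned trend with day was therefore not run. Lineage barcodes were not analysed here.

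The files held 2407 and 2044 cells for human replicates 1 and 2 and 1881 and 2783 cells for mouse replicates 1 and 2. Their total depths were 28577630, 32803173, 38166382 and 83969715 UMIs, with medians of 11137, 15766, 19122 and 28792 UMIs per cell. The number of gene entries was 32739 and 56832 in the human files and 27999 and 54087 in the mouse files, so replicates of a species had been counted on different annotations. Symbols were upper-cased and counts of entries that shared a symbol were added. The 15472 symbols found in all 4 parts were used for every test between or across species, and 29571 human and 20662 mouse symbols were available within a species.

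Cells needed at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs. This removed 15, 215, 5 and 77 cells from human replicates 1 and 2 and mouse replicates 1 and 2. Scrublet, as built into scanpy 1.11.5 with an expected rate of 5%, removed 11, 24, 5 and 32 more as doublets. The 60 barcodes found in both species files of the mixed library (1.42% of 4228) were left out of both, and by the same reasoning about 61.8 pairs of cells of 1 species were expected to remain in it. The analyses used 2323, 1805, 1811 and 2674 cells. Each library part was clustered on its own with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9, random seed 1), with OLIG2 and NKX2-2 kept out of the clustering genes. This gave 13, 17, 15 and 19 clusters.

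Clusters were named from fixed marker lists of cell types, again without OLIG2 and NKX2-2. The score of a list was its mean log2 level (10 CPM added) above the mean of all clusters, and a list needed at least 3 detected markers. A cluster took the class with the highest score of at least 1, among neuronal classes where its neuronal score exceeded its progenitor score and among the other classes where the list also exceeded the progenitor list. A remaining cluster with a positive progenitor score was named progenitor-like. A cluster stayed unnamed where no list passed, where its 10 leading genes (100 CPM added) held more markers of another class, where an off-target class had no marker among them, or where its UMI counts were low. The name of each class ends in "-like", since it rests on marker transcripts alone. The details of this naming rule were set after the clusters had been seen, and the share of unnamed cells is given for each library part. Genes of handling stress were among the 10 leading genes of 2 clusters of mouse replicate 1 that were named progenitor-like. These were DDIT4 and JUN in the first, behind FABP7 and CKB, and DDIT4 in the second, behind SLC2A3 and NKX6-2. DDIT4 is also on the hypoxia list.

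Progenitor-like cells were gated on at least 1 UMI of OLIG2, a transcription factor of motor neuron progenitors, and of NKX2-2, a transcription factor of the most ventral progenitors. For the gate each cell was thinned at random to 7000 UMIs, the largest multiple of 500 that at least 80% of the cells of each part reached (83.0%, 80.9%, 96.3% and 94.3%). This left out 77, 132, 35 and 56 progenitor-like cells as too shallow. Shares have exact 95% Clopper-Pearson intervals, and a share of 0 cells with a UMI is given with the limit that 3 counts of the total allow. A class that named no cluster has no such limit. Intervals and limits cover counting error only. The background of NKX2-2 was its share in motor neuron-like cells, with both median depths. Shares were compared between species with a two-sided exact permutation test over libraries.

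For gene tests, counts were summed per library part and class, with at least 20 cells per sum. edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test) was used with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons within a species and their difference between species came from 1 fit over 32 sums of all classes, with the library part as a block and the class within species (12414 genes, 12 residual degrees of freedom). Comparisons of human with mouse cells used the 4 sums of 1 class without a block (10619 genes in OLIG2-positive progenitors, 10199 in motor neuron-like cells, 2 residual degrees of freedom). OLIG2 and NKX2-2 define the gated classes and are not results there. Markers that named the neuronal and progenitor-like clusters stayed in the tests, and their changes between those classes were set in part by the naming. The standard error is the absolute log2 fold change divided by the square root of F. DESeq2 1.42.0 was run on the same sums. Where a side held 0 counts, the fold is a lower bound against 3 counts over the group, and where it held 1 to 3 counts the ratio of summed counts is given with its exact counting interval. A fitted value of such a gene depends on the prior count and is no bound.

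The 21 gene lists that describe pathways, cell states and RNA quality were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated one, and with fry. Of 168 list tests in 8 comparisons 30 passed with the preset and 2 with the estimated correlation, both for motor neuron identity. That list holds markers that named the motor neuron-like clusters, so these 2 passes were set in part by the naming. Genes are named by a rule: up to 4 members of each list that passed, with the largest changes, and the 10 largest changes each way among genes past the threshold with a mean log2 CPM of at least 4 and the same direction in both libraries of each species concerned. Mitochondrial and ribosomal protein genes and predicted gene models were kept out of the largest changes.

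The edgeR fits were tested on simulated data with the sizes of these sums. For comparisons within a species, the tested classes were drawn at the rates of the reference class of their library. Their spread was that of a fit of the 2 compared classes alone, also where the fit over all classes was tested. Recovery in that fit need not hold for the real sums, where NKX2-2 itself was not called. The difference between species of a change within a species was not simulated. With a 4-fold change built into 100 genes, 67 were recovered between double-positive and OLIG2-only progenitors in human and 57 in mouse, 70 between motor neuron-like cells and OLIG2-only progenitors in human, and 4.26% of 94 between species in motor neuron-like cells. Genes without a change gave 0, 2, 1 and 2 false calls. A fit of the 2 progenitor classes alone recovered 79.8% and 70.7% of 4-fold changes, with 17 and 3 false calls.

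Comparisons, tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. Alternatives covered the cell filter (2000 UMIs, 1000 genes and 5% mitochondrial UMIs), Leiden resolutions 0.5 and 2, doublets kept, a gate at 2 UMIs, without thinning and at 3500 UMIs, DESeq2 and its size factors, no filter on low counts, a minimum of 50 cells, each library part left out in turn, the block, the classes of the contrast alone, and all genes of the species. Later additions were all non-neuronal clusters taken as progenitors, progenitor clusters led by at least 3 cell cycle genes left out, and list tests in the 2 classes alone. Some genes, and an alternative that rested on them, are not reported here. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Per the reference annotations, OLIG2 lies on chromosome 21 (33025935 to 33029185) and NKX2-2 on chromosome 20 (21511017 to 21522689) of GRCh38, and the mouse genes Olig2 and Nkx2-2 on chromosomes 16 (91225457 to 91228677) and 2 (147177546 to 147194243) of GRCm38.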

Results

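Single-cell transcriptomes were collected from human and mouse pluripotent stem cells on their way to motor neurons, to set a ventral progenitor domain and its neurons side by side in both species. The data came as 2 human and 2 mouse library parts: replicate 1 of each species from 1 mixed library, and replicate 2 of each from a library of its own. Total depth was 28577630 UMIs over 2407 cells in human replicate 1, 32803173 over 2044 cells in human replicate 2, 38166382 over 1881 cells in mouse replicate 1 and 83969715 over 2783 cells in mouse replicate 2. After the cell filter and doublet removal, 2323, 1805, 1811 and 2674 cells were used. All values between species rest on n = 2 library parts per species. All cells had been sorted for GFP, and every library pooled several days of differentiation that could not be told apart. A share of cells thus also reflects the sort and the days sampled. Differences between classes or species can likewise hold a difference in day.

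Motor neuron-like cells, named from MNX1, ISL1, LHX3, SLC18A3 and other fixed markers, made up 18.9% (exact 95% interval 17.3 to 20.6) of cells in human replicate 1 and 22.4% (20.5 to 24.4) in human replicate 2. They made up 12.2% (10.7 to 13.8) in mouse replicate 1 and 11.1% (9.94 to 12.4) in mouse replicate 2. The mean share was 20.6% ± 2.46 (SD, n = 2) in human and 11.7% ± 0.775 (SD, n = 2) in mouse, and the human share exceeded the mouse share by 6.69 percentage points within the mixed library and by 11.3 between the second libraries. The difference of the means, 8.99 percentage points, was 3.93 at clustering resolution 0.5 and 5.71 at resolution 2. The two-sided exact permutation p was 0.333, which is the smallest value that 2 against 2 libraries can give. Progenitor-like cells, named from SOX2, PAX6, HES5 and related genes, took close shares of 43.2% ± 1.43 in human and 44.1% ± 3.88 in mouse (exact permutation p = 1). Neurogenic-like cells, with GADD45G among the leading genes of each of their clusters, took 8.61% ± 2.93 and 10.2% ± 2.04 (exact permutation p = 0.667), and other neuron-like cells 4.56% ± 0.295 and 7.57% ± 2.41 (exact permutation p = 0.333).

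Off-target classes and unnamed clusters also differed between libraries. Neural crest or mesenchyme-like cells with COL1A2, LUM and TWIST1 made up 8.09% and 13.2% of the human replicates 1 and 2. They made up 0.823% of mouse replicate 2, and no cluster of mouse replicate 1 took that name (exact permutation p = 0.333). Epithelium or endoderm-like cells with KRT8 and KRT18 took 7.96% and 3.82% in human, 4.71% in mouse replicate 2 and no cluster of mouse replicate 1 (exact permutation p = 0.667). The cluster of human replicate 1 also had HES5 and SFRP2 among its leading genes and a progenitor score of 0.57. Whether its 185 cells are off-target is thus uncertain, and they are not in the progenitor-like share. Unnamed clusters held 7.83% and 5.10% of human cells against 20% and 27.4% of mouse cells (exact permutation p = 0.333), so a share of any named class depends on where they would belong. No cluster was named floor plate, glial precursor, mesoderm, pluripotent or endothelial in any part. A class without a cluster of its own may still lie within unnamed or other clusters, so no limit on its share follows.

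**Figure D1:**
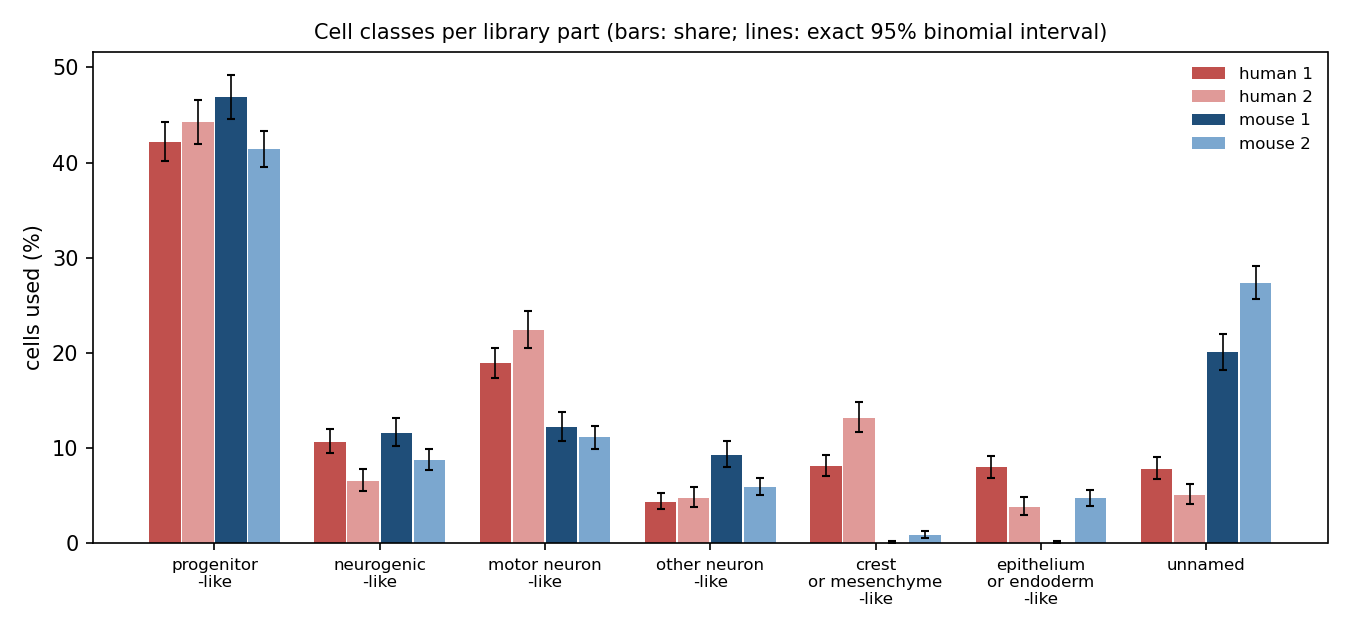
Share of the cells used (percent) in each named class, 1 bar per library part, with exact 95% binomial intervals as lines. Motor neuron-like cells stood at 18.9% and 22.4% in the human parts and at 12.2% and 11.1% in the mouse parts.

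The progenitor domain in question co-expresses OLIG2 and NKX2-2. The share of OLIG2-positive progenitor-like cells with an NKX2-2 UMI was measured at 7000 UMIs per cell. It is a rate of detection at that depth and not the size of the domain, since expressing cells can lack a UMI. In human replicate 1, 28 of 616 OLIG2-positive progenitor-like cells also held an NKX2-2 UMI, which is 4.55% (exact 95% interval 3.04 to 6.50). In human replicate 2 it was 43 of 464, or 9.27% (6.79 to 12.3), in mouse replicate 1 29 of 358, or 8.10% (5.49 to 11.4), and in mouse replicate 2 23 of 304, or 7.57% (4.86 to 11.1). The means of 6.91% ± 3.34 (SD, n = 2) in human and 7.83% ± 0.378 (SD, n = 2) in mouse differed by less than the spread between the human libraries (exact permutation p = 1), with differences of -3.56 percentage points in the mixed library and 1.70 between the second libraries. A species difference in this share was therefore not detectable with these libraries. Without thinning, the means were 12.6% ± 7.68 and 16.9% ± 2.04 (exact permutation p = 0.667). As background, OLIG2-positive motor neuron-like cells held an NKX2-2 UMI in 0 of 69 cells (up to 4.35%), 3 of 90 (3.33%, 0.693 to 9.43), 2 of 67 (2.99%, 0.364 to 10.4) and 0 of 19 (up to 15.8%) in human replicates 1 and 2 and mouse replicates 1 and 2. Over all motor neuron-like cells it was 0 of 291 (up to 1.03%) in human replicate 1 and 6 of 329 (1.82%, 0.672 to 3.93) in human replicate 2. It was 31 of 215 (14.4%, 10.0 to 19.8) in mouse replicate 1, above its progenitor share, and 0 of 280 (up to 1.07%) in mouse replicate 2. Of the 31 cells, 29 were in 1 cluster with PHOX2A and EBF1 among its leading genes. The share over all motor neuron-like cells of mouse replicate 1 is therefore no plain measure of background. Median depths before thinning were 13401, 22950, 20744 and 34835 UMIs in progenitor-like and 10028, 16582, 15011 and 25434 UMIs in motor neuron-like cells.

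OLIG2 itself was found in a larger share of human progenitor-like cells, with 68.2% and 69.7% in human replicates 1 and 2 against 44.0% and 28.9% in mouse replicates 1 and 2. The means were 68.9% ± 1.03 and 36.5% ± 10.6 (SD, n = 2 each), 24.2 percentage points apart in the mixed library and 40.7 between the second libraries (exact permutation p = 0.333). The progenitor-like classes need not be alike, since naming asked only for a positive progenitor score within each part. Scores of their clusters ran from 0.61 to 1.08 in human and from 0.08 to 1.82 in mouse. How far the naming set this gap was not tested. Among NKX2-2-positive progenitor-like cells, OLIG2 was found in 84.8%, 61.4%, 37.2% and 59.0%. NKX2-2 was also found among OLIG2-negative progenitor-like cells, in 1.74% and 13.4% in human and 10.7% and 2.14% in mouse. In neurogenic-like cells OLIG2 was found in 90.1%, 93.6%, 61.9% and 73.7%, while NKX2-2 among their OLIG2-positive cells was at 1.04%, 3.92%, 0.80% and 1.21%.

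**Figure D2:**
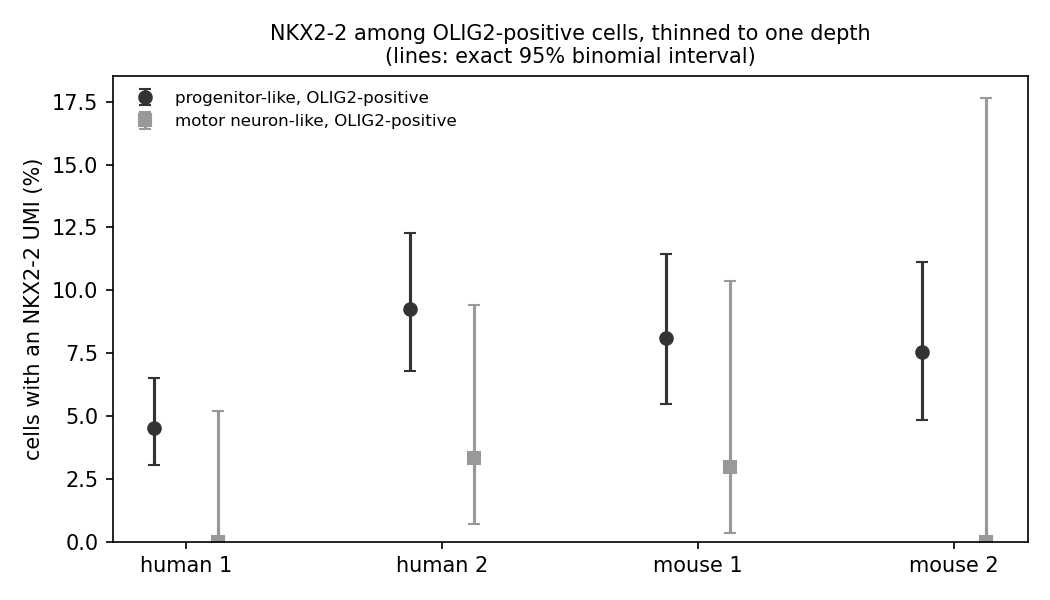
Share (percent) of OLIG2-positive cells with an NKX2-2 UMI at 7000 UMIs per cell, in progenitor-like cells and in neurons of each library part, with exact 95% binomial intervals as lines. The progenitor shares were 4.55%, 9.27%, 8.10% and 7.57% in human replicates 1 and 2 and mouse replicates 1 and 2.

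Levels of fixed genes in the classes of each library part are given as CPM of summed counts. SOX2, NKX6-1, NEUROG2, ISL1, MNX1 and LHX3 had helped to name the clusters, and OLIG2 and NKX2-2 defined the gates. Their levels therefore do not test the classes. NKX2-2 stood at 83.3, 98.9, 110 and 89.0 CPM in double-positive progenitors of human replicates 1 and 2 and mouse replicates 1 and 2, and at 2.82, 6.64, 6.58 and 4.51 CPM in OLIG2-only progenitors. OLIG2 stood at 317, 332, 207 and 231 CPM in OLIG2-only progenitors and at 50.6, 73.6, 112 and 10.9 CPM in motor neuron-like cells. SOX2, a progenitor factor, was at 394, 473, 185 and 172 CPM in OLIG2-only progenitors and at 22.0, 31.5, 37.1 and 2.32 CPM in motor neuron-like cells. NEUROG2, a proneural factor, was highest in neurogenic-like cells (458, 307, 197 and 262 CPM), and in double-positive progenitors it was at 125 and 48.9 CPM in human and at 1.83 and 10.3 CPM in mouse. The motor neuron factors ISL1 (142, 359, 354 and 407 CPM), MNX1 (68.3, 324, 129 and 261 CPM) and LHX3 (89.5, 84.9, 106 and 270 CPM) are given for the motor neuron-like cells that they had helped to name. ONECUT2 reached 86.6, 214, 101 and 184 CPM there and 390, 707, 328 and 821 CPM in other neuron-like cells. NKX6-1 was at 41.0 and 34.7 CPM in human and 282 and 97.4 CPM in mouse motor neuron-like cells. NFIA, a late temporal factor, was at 0.938 and 3.68 CPM in human and 6.28 and 21.9 CPM in mouse OLIG2-only progenitors, and NFIB at 1.41 and 1.84 against 11.4 and 34.2 CPM. SIM1, a factor of the V3 neurons born from the NKX2-2 domain, had 0 UMIs in both OLIG2-positive progenitor classes of each part and at most 4.27 CPM, in other neuron-like cells of mouse replicate 2.

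Double-positive progenitors were compared with OLIG2-only progenitors to ask how the NKX2-2 domain differs from its neighbour. The day of each cell was not known, so a difference in day between these classes cannot be told apart from one in domain. The OLIG2-only class can also hold cells whose NKX2-2 transcripts were missed at the depth of the gate. In mouse, NEUROG2 was lower (log2 fold change -3.59 ± 1.05, SE) and FABP7, a radial glia gene, higher (2.20 ± 0.67) in double-positive cells at unadjusted p under 0.05 in the edgeR fit over all classes. Neither passed adjustment over all genes, with adjusted p of 0.916 and 0.918. In human the same fit gave -0.62 ± 0.62 for NEUROG2, -0.18 ± 0.64 for FABP7 and 1.46 ± 0.53 for NTRK2. In edgeR 0 genes passed adjustment in human, in mouse and for the difference between species, where 426, 591 and 354 of 12414 genes had an unadjusted p under 0.05 and DESeq2 called 0, 1 and 0. NKX2-2, which was gated on and had to differ, reached 4.25 ± 1.02 in human and 4.02 ± 0.97 in mouse with adjusted p of 1 and 0.722, so a count of 0 in this fit is no evidence of like profiles.

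Among gene lists in that fit, glial precursor genes were higher in mouse double-positive cells (adjusted p = 6.07e-05, and 0.134 with an estimated correlation). Their 16 measured members gave 3 higher adjusted over the list alone, and radial glia genes gave 3 of 17 (adjusted p = 0.0113, and 0.660 with an estimated correlation). Proneural genes (adjusted p = 0.0113), S phase genes (8.73e-03), oxidative phosphorylation genes (4.09e-06) and proteasome genes (6.07e-05) were lower in mouse double-positive cells, each at 0.660 with an estimated correlation. In human, HOX genes were higher (2.99e-04, and 0.420 with an estimated correlation). Late temporal factors were higher (0.0254) and oxidative phosphorylation (6.92e-07) and proteasome genes (0.0200) lower in human, with 0.609, 0.609 and 0.773 with an estimated correlation. These 3 calls ended with DESeq2 size factors (adjusted p = 0.0630, 0.168 and 0.454), which moved the median of all genes in this comparison from -0.15 to -0.02. The other lists did not pass in either species, and 0 of 21 lists passed camera for the difference between species, with 1 at an unadjusted p under 0.05 and 0 by fry. Median, mean and test did not share a sign for G2/M, hypoxia, motor neuron identity, neuronal maturation, Notch, radial glia and V3 domain genes in human, or for glycolysis, HOX and Notch genes in mouse. For the difference the same held for S phase, mitochondrially encoded, Sonic hedgehog, late temporal and V3 domain genes.

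A fit of those 2 classes alone gave genes past the threshold in both species, and it also made 17 and 3 false calls in human and mouse on simulated data. It rests on 2 library parts a side per species, so its tests lean on a spread shared over genes. Its small p-values therefore overstate what replication shows, and the fit over all classes called none of these genes. In mouse, 101 genes were higher and 65 lower in double-positive cells. IGFBP5 rose by 2.64 ± 0.23 (adjusted p = 9.9e-28), PLEKHB1 by 3.18 ± 0.68, from only 11 UMIs in double-positive and 17 in OLIG2-only cells, and NTRK2 by 2.13 ± 0.47. Radial glia and glial precursor genes were higher too, with FABP7 at 2.13 ± 0.14 (5.1e-47), PTPRZ1 at 2.23 ± 0.21 (9.5e-24) and TTYH1 at 1.92 ± 0.24, as were the late temporal factors NFIA at 1.59 ± 0.34 and SOX9 at 0.93 ± 0.19. Of 12 glial precursor genes 6 were higher and 0 lower (8 adjusted over the list alone; list adjusted p = 1.52e-09, and 0.391 with an estimated correlation). Of 17 radial glia genes 6 were higher and 2 lower (7 and 2 adjusted over the list alone; 1.60e-04, and 0.391 with an estimated correlation). NEUROG2 (-3.50 ± 0.40, adjusted p = 7.4e-15), SFRP2 (-2.30 ± 0.20), IRX3 (-2.76 ± 0.57) and CCND2 (-1.01 ± 0.13) were lower. NEUROG2 held only 6 UMIs and IRX3 only 4 in double-positive cells, against 921 and 352 in OLIG2-only cells. Of 29 S phase genes 0 were higher and 2 lower (13 adjusted over the list alone; 1.13e-09, and 0.391 with an estimated correlation).

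In human, the fit of those 2 classes alone gave 13 genes higher and 27 lower. NTRK2 (1.69 ± 0.22, adjusted p = 9.6e-11), POU3F3 (1.44 ± 0.27), the late temporal factor ZFHX4 (1.35 ± 0.29) and the stress genes FOS (0.94 ± 0.14) and JUN (0.58 ± 0.15) were higher. Of 19 stress genes, a list of RNA quality, 2 were higher and 0 lower (3 adjusted over the list alone; 0.0204, and 0.525 with an estimated correlation). PTN (-2.01 ± 0.44), IRX3 (-1.91 ± 0.49), the Notch ligand DLL1 (-1.46 ± 0.31), LIN28A (-1.27 ± 0.29), SFRP2 (-1.18 ± 0.15, 8.1e-11) and CCND2 (-0.77 ± 0.17) were lower. CRABP1, with 1 UMI in double-positive cells, was lower by a ratio of 12.8 (95% counting interval 2.27 to 509). This rested on human replicate 2 (0 against 16.9 CPM), since human replicate 1 had 2.62 against 3.14 CPM. Of 29 S phase genes 0 were higher and 2 lower (17 adjusted over the list alone; 4.56e-07, and 0.525 with an estimated correlation), and of 18 proneural genes 0 were higher and 1 lower (9 adjusted over the list alone; 4.55e-04, and 0.465 with an estimated correlation). With the preset correlation, glial precursor, HOX and late temporal genes were also higher in human, and cell cycle exit, glycolysis, oxidative phosphorylation, proteasome, early temporal and mitochondrially encoded genes lower. Among the higher lists 0 of 12, 0 of 26 and 1 of 12 members passed, in that order. Among the lower lists it was 1 of 11, 0 of 20, 0 of 61, 0 of 31, 1 of 5 and 0 of 12. The median of all genes in this human comparison was itself -0.10. Medians of -0.16 for glycolysis, -0.14 for oxidative phosphorylation, -0.16 for proteasome and -0.17 for mitochondrially encoded genes lay little below it. List tests of this fit were not repeated with DESeq2 size factors. Adjusted over the list alone, glial precursor genes went 4 up and 1 down, and HOX genes 6 and 1. In mouse, G2/M, hypoxia, neuronal maturation, late temporal and V3 domain genes were also higher, and cell cycle exit, proneural, oxidative phosphorylation, proteasome and mitochondrially encoded genes lower. In that order 3 of 42, 1 of 10, 1 of 19, 3 of 12 and 1 of 3 members passed as higher. For the lower lists it was 2 of 11, 2 of 18, 0 of 61, 0 of 31 and 0 of 12. The median of all genes was -0.03 in mouse, against -0.13 for oxidative phosphorylation, -0.15 for proteasome and -0.16 for mitochondrially encoded genes. Late temporal genes had a median of 0.127 but a mean of -0.051 in mouse. With an estimated correlation 0 lists passed in this fit. The difference between species, human change minus mouse change, passed for 37 genes, 8 above 0 and 29 below. It was 2.85 for NEUROG2 and -2.27 for FABP7, -2.45 for PTPRZ1 and -3.34 for IGFBP5. Radial glia genes went 0 above and 3 below of 17 (4 adjusted over the list alone; 0.0349, and 0.785 with an estimated correlation).

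Motor neuron-like cells were compared with OLIG2-only progenitors to describe neuronal production in human. The neurofilament gene NEFM rose by 8.18 ± 0.42 (log2, SE; adjusted p = 4.1e-10), the microtubule regulators STMN2 and STMN4 by 8.08 ± 0.52 and 8.69 ± 0.62, the motor neuron factor ISL1 by 8.21 ± 0.80 and the choline transporter SLC5A7 by 7.98 ± 0.50. All 19 measured neuronal maturation genes rose (19 adjusted over the list alone; list adjusted p = 3.45e-13, and 0.128 with an estimated correlation), as did 21 of 26 motor neuron identity genes, with 0 falling (21 up and 1 down adjusted over the list alone; 2.46e-10, and 0.0295 with an estimated correlation). Both lists hold markers that had served to name the clusters, among them NEFM, STMN2, ISL1 and SLC5A7. Their rise was thus set in part by the naming and does not test it. Other large rises were those of SST at 9.10 ± 0.46, PPP1R17 at 8.35 ± 0.97, ECEL1 at 7.26 ± 0.41 and NRG1 at 7.19 ± 0.52. TTC9B had 0 UMIs in OLIG2-only progenitors and was at least 322-fold higher, against 3 counts over the group. RET was higher by a ratio of 162 (95% counting interval 54.7 to 788). In all, 2140 genes rose and 2609 fell of 12414 tested, 5764 had an unadjusted p under 0.05, and DESeq2 called 4487.

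Cell cycle genes fell together in human. MKI67 changed by -7.80 ± 0.75 (adjusted p = 2.3e-07), NUSAP1 by -7.39 ± 0.68 and RRM2 by -6.60 ± 0.79, and all 42 G2/M genes (list adjusted p = 4.58e-21) and all 29 S phase genes (1.90e-11) fell, adjusted over the list alone too. Both lists were at 0.382 with an estimated correlation. DLGAP5 was lower by a ratio of 723 (130 to 28595). Of 17 radial glia genes 0 rose and 10 fell (12 adjusted over the list alone; 3.24e-03, and 0.382 with an estimated correlation), among them SOX2 (-4.18 ± 0.85), PROM1 and HES1. In the Notch list 6 rose and 10 fell of 22 (7 and 10 adjusted over the list alone; 0.542), with HES1 at -6.19 ± 0.93, HES5 at -5.55 ± 1.26 and NOTCH2 at -4.75 ± 0.61, and its median and mean differed in sign. In the Sonic hedgehog list 1 rose and 8 fell of 16 (2 and 10 adjusted over the list alone; 0.114). GLI1 had 0 UMIs in motor neuron-like cells and was at least 38.9-fold lower, and GLI3 changed by -4.20 ± 0.56 and PTCH1 by -2.73 ± 0.41. SOX2, HES1 and HES5 had helped to name the progenitor-like clusters, so their falls were set in part by the naming.

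Of 18 proneural genes 11 rose and 0 fell in human (12 up adjusted over the list alone; 1.12e-03, and 0.542 with an estimated correlation), with NHLH2 at 5.63 ± 0.45 and NEUROD1 at 5.34 ± 0.65. The temporal factors POU2F2 (4.37 ± 0.34), ONECUT2 (4.47 ± 0.56), NFIA (2.36 ± 0.82) and ZBTB20 (2.15 ± 0.34), which is on the glial precursor list, rose, while HMGA2 (-3.26 ± 0.53) and SOX9 (-1.93 ± 0.39) fell. HOX genes rose, 12 up and 1 down of 28 (13 and 2 adjusted over the list alone; 4.17e-03, and 0.382 with an estimated correlation), led by HOXC8 (2.48 ± 0.29), HOXC9 (1.78 ± 0.36) and HOXB5 (1.76 ± 0.31). CRABP1 rose by 5.11 ± 1.21 and ID3 changed by -4.40 ± 0.52. The list test did not pass for the remaining lists: WNT, BMP and retinoic acid genes (2 up, 11 down of 26), early (3, 2 of 6) and late (4, 1 of 14) temporal factors, cell cycle exit (4, 2 of 11), V3 domain (0, 2 of 8), glial precursor (3, 3 of 16), glycolysis (5, 9 of 20), hypoxia (3, 2 of 12), oxidative phosphorylation (6, 9 of 61), proteasome (1, 6 of 31), stress (4, 1 of 19) and mitochondrially encoded genes (0, 2 of 12). Adjusted over the list alone these counts were the same, except for glycolysis (6, 10), oxidative phosphorylation (6, 6), V3 domain (0, 0) and mitochondrially encoded genes (0, 0). Median and mean differed in sign for oxidative phosphorylation, and the test from both for cell cycle exit. Without human replicate 1 the count of called genes was 2088 and without human replicate 2 it was 1600.

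In mouse the same comparison asked for the matching change. SLC18A3, the vesicular acetylcholine transporter, rose by 9.31 ± 0.77 (log2, SE; adjusted p = 1.1e-07), STMN2 and ECEL1 by 8.70 ± 0.56 and 8.70 ± 0.53, NEFM by 8.57 ± 0.44 (2.6e-10) and INA by 7.46 ± 0.39. CHAT, RBFOX1, SLC5A7 and ACHE had 0 UMIs in OLIG2-only progenitors and were at least 253-fold, 317-fold, 64.1-fold and 60.3-fold higher. ISL2 was higher by a ratio of 497 (137 to 4114). All 19 neuronal maturation genes rose (19 adjusted over the list alone; 1.31e-13, and 0.110 with an estimated correlation) and 22 of 26 motor neuron identity genes, with 0 falling (22 adjusted over the list alone; 2.42e-10, and 0.0279 with an estimated correlation). As in human, both lists hold markers that had served to name the clusters, among them SLC18A3, STMN2, NEFM, INA, CHAT, SLC5A7 and ISL2. Their rise was thus set in part by the naming and does not test it. In all, 2556 genes rose and 2643 fell, 6113 had an unadjusted p under 0.05 and DESeq2 called 4913. Leaving out mouse replicate 2 gave 2348.

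Mouse cell cycle genes fell as well, with AURKB at -4.79 ± 0.57, CDK1 at -4.21 ± 0.52 and CDC6 at -6.24 ± 0.75. Of 42 G2/M genes 41 fell and 0 rose (41 adjusted over the list alone; 1.23e-16), and all 29 S phase genes fell (29 adjusted over the list alone; 2.10e-12). Both were at 0.388 with an estimated correlation. The radial glia list holds markers that named the progenitor-like clusters, HES1 among them, so its fall was set in part by the naming. Of 17 radial glia genes 1 rose and 12 fell (the same adjusted over the list alone; 2.68e-03, and 0.388 with an estimated correlation), with SLC1A3 at -6.58 ± 0.71 and CRB2 at -4.36 ± 0.56. Sonic hedgehog genes fell, 0 up and 9 down of 16 (10 adjusted over the list alone; 3.59e-03, and 0.388 with an estimated correlation), with GLI1 at -5.66 ± 0.71 and GLI2 at -4.08 ± 0.96. In the Notch list 6 rose and 9 fell of 22 (the same adjusted over the list alone), with DLL3 at 5.08 ± 0.67, NOTCH3 at -4.68 ± 0.54 and HES1 at -3.94 ± 0.77. Of 18 proneural genes 10 rose and 0 fell (10 adjusted over the list alone; 1.38e-03, and 0.485 with an estimated correlation), with NHLH2 at 7.10 ± 0.45, NHLH1 at 6.25 ± 0.83 and NEUROD1 at 4.96 ± 0.67.

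Among temporal factors in mouse, ONECUT2 (5.93 ± 0.64), POU2F2 (3.38 ± 0.31), TGFB2 (3.08 ± 0.67) and NR2F2 (2.31 ± 0.27) rose and HMGA2 (-4.17 ± 0.58) and NFIB (-3.00 ± 0.57) fell. HOX genes went 8 up and 1 down of 28 (the same adjusted over the list alone; 0.148), with HOXC6 at 2.56 ± 0.32 and HOXC4 at 1.72 ± 0.21. CDKN1C, a cell cycle inhibitor, rose by 2.89 ± 0.32. Glial precursor genes went 1 up and 6 down of 16, with FGFR3 at -4.19 ± 0.44 and PTPRZ1 at -3.01 ± 0.61. WNT, BMP and retinoic acid genes went 5 up and 11 down of 26, with WNT7B at -4.96 ± 0.86 and SFRP2 at -4.91 ± 0.70. The list test did not pass for either or for the other lists: early (3 up, 2 down of 6) and late (5, 1 of 14) temporal factors, cell cycle exit (3, 3 of 11), V3 domain (2, 1 of 8), glycolysis (5, 5 of 20), hypoxia (5, 1 of 12), oxidative phosphorylation (1, 5 of 61), proteasome (1, 2 of 31), stress (2, 2 of 19) and mitochondrially encoded genes (0, 0 of 12). Adjusted over the list alone these counts and the previous ones were the same, except for WNT, BMP and retinoic acid (5, 13), early temporal factors (3, 3), cell cycle exit (4, 3), oxidative phosphorylation (1, 1) and proteasome genes (0, 0). Median, mean and test did not share a sign for cell cycle exit and oxidative phosphorylation.

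**Figure D3:**
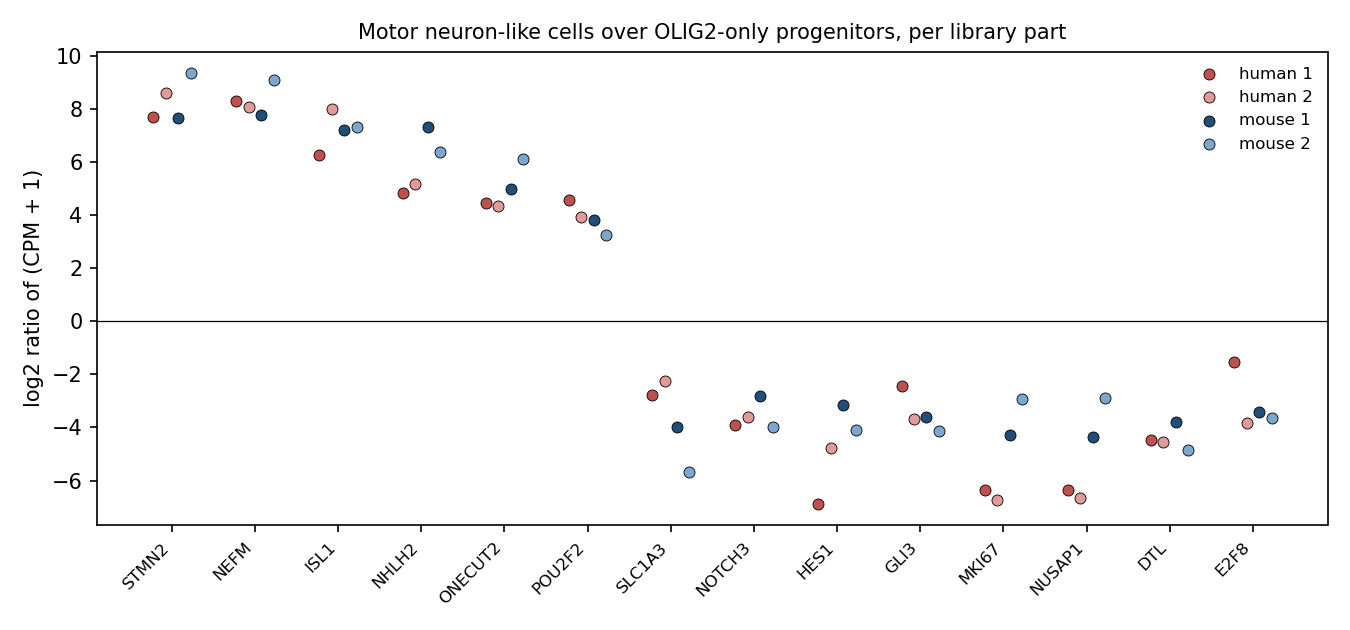
Log2 ratio of CPM plus 1 in motor neuron-like cells over OLIG2-only progenitors, 1 point per library part, for selected genes. NEFM and STMN2 lay far above 0 and MKI67 far below 0 in all 4 library parts. NEFM and STMN2 had helped to name the neuronal clusters.

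The change towards motor neurons differed between human and mouse for 1180 genes, with the human change above the mouse change for 469 and below it for 711. CCND2, a cyclin, did not pass in human (-1.06 ± 0.49, adjusted p = 0.0938) and fell in mouse (-5.91 ± 0.60), a difference of 4.85 ± 0.73 (adjusted p = 3.7e-04). ZWINT, a kinetochore gene, changed by -6.18 ± 0.58 in human and 1.00 ± 0.39 in mouse, a difference of -7.19 ± 0.70 (6.0e-06). The hypoxia gene ADM changed by -3.42 ± 0.51 and 2.11 ± 0.59 (difference -5.53 ± 0.78, 2.4e-04). MOXD1 changed by 0.49 ± 0.48 in human (adjusted p = 0.463) and -5.45 ± 0.67 in mouse (difference 5.94 ± 0.84, 2.4e-04), and PDLIM1 by 2.17 ± 0.43 and -3.25 ± 0.53 (difference 5.41 ± 0.68, 9.7e-05).

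DLK1 changed by -4.02 ± 0.85 in human and 2.05 ± 0.73 in mouse (difference -6.07 ± 1.12), and DIO3 and CTHRC1 had differences of -6.04 ± 1.03 and -5.84 ± 0.96. The glutamate transporter SLC1A3 fell in both, by -2.89 ± 0.54 and -6.58 ± 0.71 (difference 3.69 ± 1.00, adjusted p = 0.0250). G2/M genes fell further in human, with 0 above and 11 below of 42 (1 and 25 adjusted over the list alone; list adjusted p = 2.85e-06, and 0.930 with an estimated correlation). Glial precursor genes went 4 above and 0 below of 16 (6 and 0 adjusted over the list alone), neuronal maturation 1 and 5 of 19 (1 and 6), motor neuron identity 2 and 2 of 26 (2 and 5), HOX 1 and 3 of 28 (2 and 3), glycolysis 1 and 3 of 20 (1 and 4), oxidative phosphorylation 4 and 2 of 61 (6 and 2) and radial glia 3 and 2 of 17 (5 and 4). The other lists had 0 to 3 genes each that passed: S phase 2 above and 1 below of 29, cell cycle exit 2 and 0 of 11 (2 and 2), hypoxia 0 and 2 of 12 (2 and 3), late temporal 1 and 2 of 14, early temporal 0 and 1 of 6, proneural 1 and 1 of 18 (1 and 2), stress 1 and 0 of 19, Notch 1 and 0 of 22, WNT, BMP and retinoic acid 1 and 0 of 26 (0 and 0), and Sonic hedgehog, proteasome, V3 domain and mitochondrially encoded genes 0. Median, mean and test did not share a sign for cell cycle exit, S phase, radial glia, WNT, BMP and retinoic acid, or early and late temporal factors. Of 12414 genes 2987 had an unadjusted p under 0.05 and DESeq2 called 1366. The count fell to 204 without human replicate 1, 137 without human replicate 2 and 507 without mouse replicate 2, and to 532 without progenitor clusters led by cell cycle genes.

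Human and mouse OLIG2-positive progenitors were then compared directly, where a fold also holds differences between the gene models of each species. Several HOX genes of paralog numbers 6 to 9 were higher in human, HOXC8 by 7.34 ± 0.85 (log2, SE; adjusted p = 1.4e-03), HOXC6 by 6.37 ± 0.68 and HOXC9 by 6.27 ± 0.92, and HOXA9 by a ratio of 419 (74.8 to 16563). HOXB1 (3.33 ± 0.45) and HOXD1 (3.84 ± 0.56), of paralog number 1, were higher too, while HOXB7 (0.85 ± 0.37) and HOXB8 (-0.79 ± 0.39) did not pass. These 4 were named after their values were seen. HOXA6 (3.12 ± 1.08) and HOXB6 (-1.19 ± 0.59), named likewise, did not pass either. HOXA5 (-2.59 ± 0.33), HOXB5 (-2.78 ± 0.61) and HOXA2 (-2.27 ± 0.33) were lower. Of 26 HOX genes 9 were higher and 3 lower (10 and 4 adjusted over the list alone; list adjusted p = 0.213). The late temporal factors NFIB (-3.87 ± 0.60), NFIA (-2.60 ± 0.78) and POU2F2 (-2.53 ± 0.44) were lower and TGFB2 (3.23 ± 0.91) higher in human, 1 higher and 4 lower of 12 (the same adjusted over the list alone). OLIG2 (0.45 ± 0.30), NKX2-2 (-0.32 ± 0.51), NEUROG2 (0.76 ± 0.31) and NKX6-1 (-0.92 ± 0.33) did not pass. In all, 1967 genes were higher and 1435 lower in human of 10619, 4690 had an unadjusted p under 0.05 and DESeq2 called 3710. Without mouse replicate 1 the count was 1827, and without mouse replicate 2 it was 1682.

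Members of the radial glia, proneural and Notch lists also differed in OLIG2-positive progenitors. Of 17 radial glia genes 6 were higher and 0 lower in human (the same adjusted over the list alone), with TTYH1 at 5.29 ± 0.48, NES at 2.45 ± 0.43, CRB2 at 2.22 ± 0.50 and FABP7 at 2.08 ± 0.64. SOX2 was at 1.15 ± 0.31 (adjusted p = 0.0248). Proneural genes went 7 higher and 2 lower of 18 (8 and 3 adjusted over the list alone), with NHLH1 at 5.14 ± 0.63. Notch genes went 6 and 3 of 21 (8 and 3), with HES6 at 3.04 ± 0.33, DLL3 at 2.82 ± 0.51 and MFNG at -2.34 ± 0.45. The cyclin CCND1 was higher (3.32 ± 0.35) and CCND3 (-2.93 ± 0.49) and CCND2 (-2.82 ± 0.51) lower. S phase genes went 1 and 7 of 29 (1 and 7), with MCM6 at -1.96 ± 0.30, and G2/M genes 6 and 3 of 42 (5 and 3), with CENPA at -2.70 ± 0.35. Neuronal maturation genes went 7 and 3 of 19 (8 and 3), with SYT1 at 5.69 ± 0.63 and GAP43 at -4.09 ± 0.42.

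Housekeeping lists were lower in human OLIG2-positive progenitors. Of 31 proteasome genes 0 were higher and 11 lower (12 adjusted over the list alone; 5.05e-04, and 0.739 with an estimated correlation), with PSMA6 at -3.99 ± 0.33 (7.3e-04), PSMD12 at -2.08 ± 0.35 and PSMB4 at -2.03 ± 0.30. Of 61 oxidative phosphorylation genes 1 was higher and 10 lower (1 and 8 adjusted over the list alone; 0.0338, and 0.739 with an estimated correlation), with SDHB at -2.48 ± 0.44 and SDHD at -1.87 ± 0.31. Stress genes went 7 higher and 1 lower of 19 (7 and 2; 0.191), with HSPA1B at 4.10 ± 0.59, HSPA1A at 4.03 ± 0.58 and HSPA8 at -2.39 ± 0.42. CRABP1 (-6.06 ± 0.82) and CYP26B1 (-4.26 ± 0.77), genes of retinoic acid handling, were lower and the WNT target LEF1 (3.98 ± 0.59) higher. WNT, BMP and retinoic acid genes went 5 and 5 of 23, Sonic hedgehog 1 and 3 of 13, cell cycle exit 3 and 2 of 11, glial precursor 2 and 3 of 11, glycolysis 4 and 3 of 20, hypoxia 2 and 2 of 11, motor neuron identity 2 and 2 of 16, V3 domain 0 and 1 of 4, early temporal 1 and 0 of 5 and mitochondrially encoded 4 and 0 of 12, the same adjusted over the list alone except for cell cycle exit (3 and 3). Median, mean and test did not share a sign for cell cycle exit, glial precursor, motor neuron identity and WNT, BMP and retinoic acid genes. BOLA2 was at -10.92 ± 0.50 and DDC at -8.18 ± 0.73, and CCNB1IP1 at least 1465-fold higher and PEG3 at least 671-fold lower in human.

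**Figure D4:**
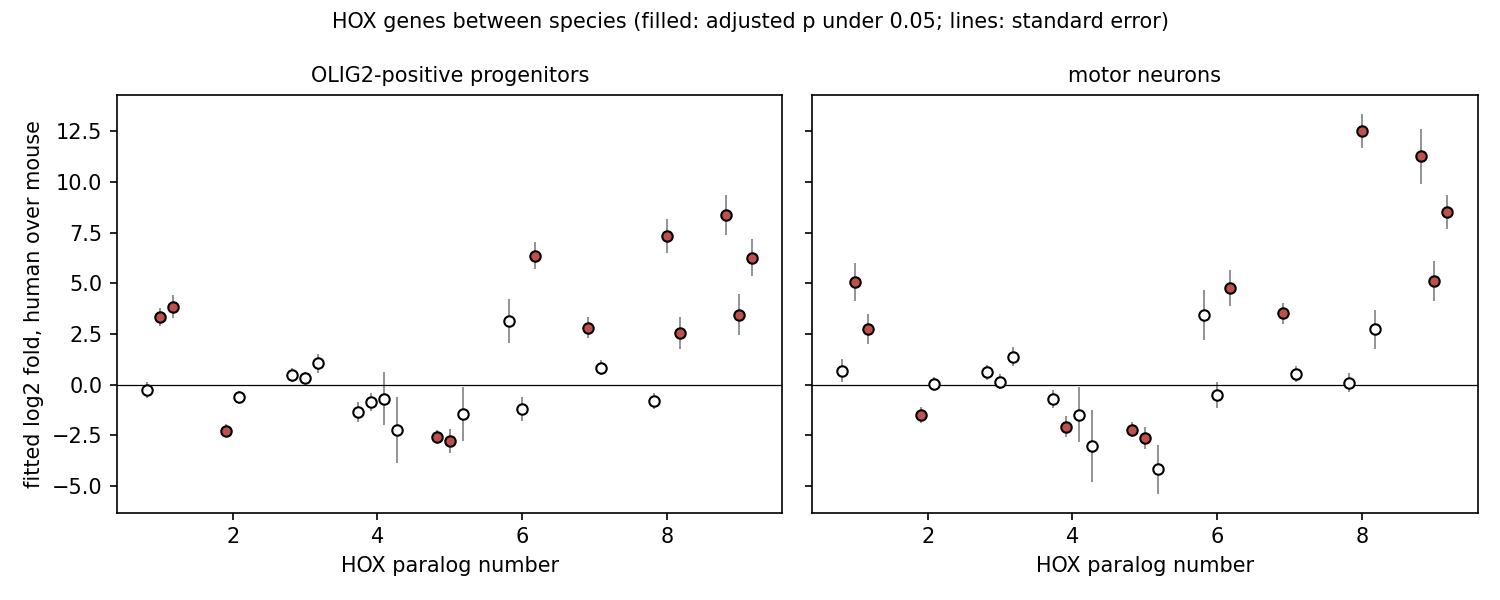
Fitted log2 fold change, human over mouse, of each HOX gene against its paralog number, in OLIG2-positive progenitors and in motor neuron-like cells, with filled points for an adjusted p under 0.05 and lines for the SE. HOXC8, HOXC9 and HOXC6 lay above 0 and HOXA5 and HOXB5 below 0 in both classes.

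In motor neuron-like cells the comparison of human with mouse asked whether species differences extended to the neurons. HOXC9 (8.54 ± 0.83, log2, SE; adjusted p = 6.7e-03), HOXB9 (5.12 ± 0.99) and HOXC6 (4.78 ± 0.89) were higher in human, HOXA9 at least 184-fold and HOXC8 by a ratio of 7996 (1435 to 315860). HOXB1 (5.07 ± 0.96) and HOXD1 (2.75 ± 0.75) were higher as well, while HOXA5 (-2.22 ± 0.37) and HOXB5 (-2.65 ± 0.55) were lower. Of 26 HOX genes 8 were higher and 4 lower (11 and 5 adjusted over the list alone; 0.0502, which passed at 0.0480 with DESeq2 size factors). EBF1 (-4.23 ± 0.62) and CHAT (-4.04 ± 0.90) were lower and ONECUT1 (3.28 ± 0.46) higher, 2 higher and 4 lower of 25 motor neuron identity genes (3 and 5). MNX1 (-0.02 ± 0.67) and ISL1 (-0.65 ± 0.46) did not pass. Of 28 G2/M genes 0 were higher and 9 lower (1 and 14 adjusted over the list alone; 9.04e-05, and 0.829 with an estimated correlation), with CENPA at -5.40 ± 0.62, CDCA8 at -4.71 ± 0.65 and BIRC5 at -2.74 ± 0.62. In all, 1067 genes were higher and 725 lower in human of 10199, 3410 had an unadjusted p under 0.05 and DESeq2 called 2342. Leaving out human replicates 1 and 2 and mouse replicates 1 and 2 in turn gave 645, 730, 1099 and 714.

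Stress and proteasome genes also passed the list test in motor neuron-like cells with the preset correlation alone. Stress genes went 5 higher and 1 lower of 19 (6 and 2 adjusted over the list alone; 0.0290, and 0.829 with an estimated correlation), with HSPA1B at 5.49 ± 0.70, HSPA1A at 5.13 ± 0.59 and ATF3 at 3.29 ± 0.50. Proteasome genes went 0 and 8 of 31 (0 and 9; 1.00e-04, and 0.829 with an estimated correlation), with PSMA6 at -3.45 ± 0.39 and PSMB4 at -2.10 ± 0.35, and oxidative phosphorylation genes 0 and 5 of 61 (0 and 1; 0.0502), with SDHD at -2.80 ± 0.39. Radial glia genes were 4 higher and 1 lower of 16 (5 and 1), with CRB2 at 5.44 ± 0.76, FABP7 at 5.32 ± 0.50 and NES at 4.47 ± 0.43. ENO2, a neuronal glycolysis gene, was higher by 6.43 ± 0.64, TUBB3 lower (-4.32 ± 0.92), and among S phase genes (2 and 4 of 26) UNG was at 4.41 ± 0.60 and RRM2 at -4.52 ± 0.71. CYP26B1 (-6.08 ± 0.65), DHRS3 (4.03 ± 0.47) and SFRP2 (3.30 ± 0.48) differed among WNT, BMP and retinoic acid genes (4 and 2 of 19, and 4 and 4 adjusted over the list alone). The other lists gave 4 and 1 of 20 for glycolysis (4 and 5 adjusted over the list alone), 2 and 1 of 10 for glial precursor (3 and 1), 2 and 0 of 19 for Notch (4 and 0), 0 and 2 of 12 for late (0 and 4) and 1 and 0 of 6 for early temporal factors, 1 and 1 of 19 for neuronal maturation, 0 and 1 of 18 for proneural, 1 and 0 of 10 for Sonic hedgehog, 0 and 0 of 10 for cell cycle exit, 0 and 1 of 11 for hypoxia, 0 and 1 of 3 for V3 domain and 0 and 0 of 12 for mitochondrially encoded genes. Median, mean and test did not share a sign for cell cycle exit, Sonic hedgehog and radial glia genes. TMSB15A was at least 1284-fold higher and ZFP57 at least 287-fold lower in human, and CD9 was lower by a ratio of 1355 (243 to 53568).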

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

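No tests in this part were chosen only after the result was seen. Each result here is a change that differed between human and mouse cells in a test of the difference itself, with the human change minus the mouse change as its value on the log2 scale. From OLIG2-only progenitors to motor neuron-like cells, 1180 genes differed. Of the 60 genes named by rule for this difference, 55 lost the call in a fit without the library block. Among the largest differences, those above 0 with more than 1 UMI in each class included MOXD1 (5.94), PDLIM1 (5.41), HIST1H2AE (5.02), CCND2 (4.85), PPP1R1A (4.68) and ARHGDIG (4.49). Below 0 they included ZWINT (-7.19), DLK1 (-6.07), DIO3 (-6.04) and CTHRC1 (-5.84). Some counts were still low. ARHGDIG had 12 UMIs in human and DIO3 13 in mouse OLIG2-only progenitors. MOXD1 had 16 UMIs in mouse and ZWINT 17 in human motor neuron-like cells. PMP22 (-10.42), LAMP5 (-8.82), CD9 (-7.92), ARG2 (-7.81), TMEM169 (-6.04), DLGAP5 (-5.81), HOXC8 (5.55), TTC9B (5.38), CITED4 (4.77), ACHE (-4.63) and ONECUT1 (-4.03) also differed, but each had 0 or 1 UMI in a class of 1 species, so their fitted values depend on the prior count.

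Members of the fixed lists differed as well. G2/M genes fell further in human than in mouse, with a list adjusted p of 2.85e-06, and 0.930 with an estimated correlation. In S phase UNG differed by 3.98, in stress ATF3 by 1.51 and in glycolysis SLC16A1 by 2.19. For hypoxia ADM differed by -5.53 and for late temporal factors TGFB2 by -3.78. MIB1 of the Notch list (0.97), NDUFB8 of oxidative phosphorylation (1.19), SLC1A3 of the radial glia and glial precursor lists (3.69) and SFRP2 of the WNT, BMP and retinoic acid list (2.83) lay above 0. No explanation was tested for these genes. Counts were low for SLC1A3, with 6 UMIs in mouse motor neuron-like cells, and for TGFB2, with 12 in mouse OLIG2-only progenitors.

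Between double-positive and OLIG2-only progenitors, 37 genes differed between species in the fit of those 2 classes alone. NEUROG2 (2.85), ZDBF2 (2.63), SHROOM3 (2.32), HOXA4 (1.87), ZFHX4 (1.70), CYR61 (1.42) and SFRP2 (1.12) had the higher change in human. IGFBP5 (-3.34), PDLIM4 (-2.85), MOXD1 (-2.68), PLEKHB1 (-2.65), RTN1 (-2.48), PTPRZ1 (-2.45), FABP7 (-2.27), RGMB (-2.14), CPNE2 (-2.10) and CSPG5 (-2.01) had the lower change in human, as did the G2/M gene NUSAP1 (-0.95) and the radial glia gene TTYH1 (-1.61). SPP1 (9.04) had 0 UMIs in mouse double-positive cells and CRABP1 (-3.82) had 1 UMI in human ones, so their fitted values depend on the prior count. In the fit over all classes 0 genes differed in edgeR and 0 in DESeq2, with 354 at an unadjusted p under 0.05, so these 37 calls rest on the smaller fit. False calls of the smaller fit were not simulated for this difference.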

How the results depend on the processing

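The alternatives that left out progenitor clusters led by cell cycle genes, and tests with all non-neuronal clusters as progenitors, were chosen only after the data were seen. The difference in motor neuron-like share, 8.99 percentage points, stayed above 0 at 12.0 under the stricter cell filter, 3.93 and 5.71 at resolutions 0.5 and 2, 6.49 with doublets kept, and 7.24 to 10.7 with 1 library part left out. The difference in NKX2-2 share, -0.927, was 0.763 under the stricter filter and -4.28 without thinning. It was -2.83 with a gate at 2 UMIs (0.789% human, 3.62% mouse), -2.84 at 3500 UMIs per cell (3.02% and 5.85%) and -2.61 at resolution 0.5, and ran from -3.29 to 1.43 with 1 library part left out, the highest value coming without human replicate 1. The cause was not tested.

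Between double-positive and OLIG2-only progenitors the fit of those 2 classes alone called 41, 167 and 37 genes in human, in mouse and for their difference, counting the gated genes. In the fit over all classes, which called 0 genes, 1 gene was called in mouse under the stricter filter, at resolution 2, with doublets kept, with DESeq2 and with no filter on low counts. It was GRIA2 in the first 3, PLEKHB1 with DESeq2 and ZDBF2 with no filter, named after their values were seen. That fit also called 0 genes with each library part left out, and the fit of the 2 classes alone was not repeated that way. A gate at 2 UMIs, 3500 UMIs per cell, a minimum of 50 cells and cycling clusters left out could not be run there, since a library held too few double-positive cells.

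Counts of called genes moved with the libraries. They ran from 1600 to 5051 for motor neuron-like cells in human, from 2348 to 4645 in mouse and from 137 to 1230 for the difference. Human against mouse they ran from 1682 to 3510 in progenitors and from 645 to 1099 in motor neuron-like cells. A species left with 1 library was assumed to vary like the other. Leaving out cycling clusters gave 532 for the difference and 2193 for progenitors. The cause was not tested.

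The replicate numbers pair only the parts of the mixed library. Without the block, motor neuron-like cells gave 1697 genes in human, 2113 in mouse and 47 for the difference, and with a block the comparisons of species gave 4167 and 2250. Of 168 gene list tests 30 passed, 2 with an estimated correlation and 28 with DESeq2 size factors. The 2 were for motor neuron identity, a list with markers that named the motor neuron-like clusters.

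Each named gene was paired with each alternative. For motor neuron-like cells in human, direction and call were kept in 1582 pairs and the call was lost in 118. These counts were 1618 and 117 in mouse and 835 and 305 for the difference. Between species they were 1583 and 83 in progenitors and 1122 and 99 in motor neuron-like cells. Without the library block, 55 of the 60 named genes for the difference lost the call. FOXA2 in human came to 0 without human replicate 2, and no named gene changed sign.

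Depth limited the double-positive class, which held 28, 43, 29 and 23 cells in human replicates 1 and 2 and mouse replicates 1 and 2.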

Other observations

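Tests of cell lines, HOX genes, depth, free RNA, the library batch and a shared profile of double-positive cells were chosen only after the result was seen. Several clusters that stayed unnamed had leading genes of their own. In human replicate 2 a cluster of 16 cells was led by muscle genes, among them MYLPF, TNNC2, MYL1, DES, ACTC1 and TTN. In human replicate 1 a cluster of 135 cells was led by SYP, HSPA6 and HSPA1A, and a cluster of 47 cells by MT1X, CRABP1, HES6 and VSX1. TPM1 and TAGLN led a cluster of 154 cells in mouse replicate 1, and TAGLN, ACTA2 and H19 led one of 103 cells in mouse replicate 2. PTN, DLK1, GPC3 and ARG1 led another of 128 cells there. Epithelium-like cells of human replicate 2 also held SHH and TTR among their leading genes.

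In mouse replicate 1, a motor neuron-like cluster held an NKX2-2 UMI in 29 of 71 cells, or 40.8% (exact 95% interval 29.3 to 53.2). The other motor neuron-like clusters of the 4 parts held one in at most 3% of cells. The cluster with 29 such cells had PHOX2A, TUBB3, EBF1 and NEFM among its leading genes. It made up 72 of the 221 motor neuron-like cells that were summed for mouse replicate 1 in the gene tests. The GFP entry of the mixed library held 0 UMIs in 2407 human and 1881 mouse cells, although cells had been sorted for GFP. Whether the reference used for counting held the transgene as expressed was not given in the sources used here, so no limit on GFP-positive cells follows.

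The share of NKX2-2 among OLIG2-positive progenitors was lower in human replicate 1 (4.55%) than in human replicate 2 (9.27%). The gap was 10.9 percentage points without thinning and 4.72 at 1 depth. As a ratio of the shares it was 2.51 and 2.04, so thinning changed the ratio less. The gap at 1 depth exceeded counting error over cells (two-sided Fisher exact p = 0.00269), which argues against sequencing depth as the whole cause. That p covers no spread between libraries and does not show that the cell lines differ. Free RNA in the droplets stays open. Motor neuron-like cells of the same libraries differed by 1.82 percentage points, which is 2.90 less than the gap in progenitors, with a 95% interval from -0.78 to 6.57 (square-and-add, over cells). With 1 human library per cell line, the line and the differentiation run cannot be told apart, and either may underlie the gap. The human files were also counted on different annotations, which follows the same split and remains open.

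Several HOX genes of paralog numbers 6 to 9 were higher in human than in mouse cells, but so were HOXB1 and HOXD1. HOXA6, HOXB6, HOXB7 and HOXB8 did not pass in either class, nor did HOXD8 in motor neuron-like cells. A trend with paralog number did not pass either. Across 26 genes, Spearman's rho of paralog number and fold change was 0.347 in progenitors (two-sided permutation p = 0.0829) and 0.375 in motor neuron-like cells (permutation p = 0.0595), both at 0.0829 after Benjamini-Hochberg adjustment, and genes are not independent replicates. A p that misses 0.05 does not show that there was no relation. Gene models that differ between the annotations of the species remain open. A more posterior position of the human cells along the body axis may equally underlie the pattern.

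Proteasome and oxidative phosphorylation genes were lower in human than in mouse OLIG2-positive progenitors, 11 of 31 and 10 of 61 of them past the threshold, and both lists were at 0.739 with an estimated correlation. Reads lost to human pseudogenes as the whole cause are argued against, since members without one were as low: 52 members with a pseudogene named after them had a median of -0.60 and 40 without one -0.62, a difference of 0.0283 (permutation p = 0.810). An interval added once that value was known ran from -0.35 to 0.33. Over all 10619 genes, those with a pseudogene had a median of -0.23 and those without one 0.09, a difference of -0.31. It lies within that interval, so a part played by pseudogenes remains open. A library batch as the whole cause is also argued against, with medians of -0.44 in the mixed library and -0.58 between the second libraries and 59 of 92 members lower in both. A species difference in metabolism could underlie the pattern and was not tested, and gene models remain open too.

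A hypothesis was that double-positive progenitors of both species share a profile. Of 161 genes called in mouse with the 2 classes alone and with a fitted change other than 0 in both, 119 (73.9%) had the same sign in human, against 57.0% of 10055 genes, an excess of 16.9 percentage points. Of the 37 such genes called in human, 27 had the same sign in mouse. The 9 genes called in both all had the same sign, where 0.592 genes would be expected to be called in both if calls were independent. They were not independent, since both species shared 1 fit with 1 spread per gene. The same-sign share of all genes was also not matched on expression level. A shared profile may be present beside the species differences, but these counts do not isolate it, and genes are not independent replicates.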
